A study of Danio rerio with 12 samples.

How the data were processed

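Cells were sorted from wild-type zebrafish carrying the reporters entpd5a:Gal4FF;UAS:GFP and R2col2a1a:mCherry at 15 days post fertilisation, and 12 ATAC-seq libraries were made from 4 groups of 3. Groups and replicate numbers were taken from the sample titles, which name the libraries biological replicates. Per the labels' protocols, lysis was with digitonin and mild detergents, and the amount of transposase and the length of transposition were adjusted to the number of cells in each sample. Enzyme dose can therefore vary with group and replicate, and its values are not given in the sources used here. Per the labels, 3 libraries (replicate 1 of head osteoblasts, trunk osteoblasts and trunk chondrocytes) lost files and are represented from the alignment after the read-shifting step, in which reads are moved to the centre of the transposase cut.

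Per the submitters' processing notes, fastp, Bowtie2, SAMtools, bedtools, deepTools and MACS2 were used with the danRer11 build, with no versions or settings given in the sources used here. The deposited files are lists of MACS2 summits, one list per library, so peaks were called per library and not on pooled replicates. Each deposited row gives a position of 1 base, a peak name and a score that is the −log10 of a p-value or q-value as the peak caller wrote it. Which of the p-value and the q-value was used is not given in the sources used here. The lowest score of all lists was 1.30661, and the −log10 of 0.05 is 1.301. The scores are the authors', and they were used only to rank or filter summits within a list, because a score grows with sequencing depth. Read counts were not used here, so the depth of each library is unknown apart from its number of summits, between 8407 and 79517. Sequence names in the lists are the RefSeq names of GRCz11, the assembly that danRer11 denotes. Positions were converted to count from 1. Peak names inside 7 of the 12 lists carry another replicate number than the title, and the titles were followed.

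Summits of all 12 full lists within 250 bp of each other were chained into regions. For each contrast, every library was reduced to its strongest N summits by its own score, N being the shortest list among the libraries compared (8407, 20380 or 28911). A region separated 2 groups when every library of one group and no library of the other had a summit in it. The number of separating regions was compared with that from other splits of the same libraries, all 10 splits for 3 against 3 libraries and 100 drawn with the real one included for 6 against 6. A region held by 3 of 6 libraries falls on the real groups in 10.0% of cases by chance. Absence from a list means that no summit was called among the summits used and not that chromatin was closed. Similarity of libraries was the Jaccard index of their regions, tested by an exact one-sided permutation of the group labels.

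Regions were also counted per library in 100 kb windows of the 25 chromosomes, by the middle of the region. Windows with a mean of at least 1 region per library (9407) were tested on log2(regions + 0.5) with limma, in one model of all 12 libraries with 4 group means and the log2 list length as covariate, with trended and robust variance moderation and Benjamini-Hochberg adjustment at 0.05. The model left 7 residual degrees of freedom. A log2 difference on this scale understates the change of windows with few regions. The interaction contrast was the head difference between cell types minus the trunk difference.

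The design fixed before the data were examined assigned regions to genes and planned tests of genes, gene lists, promoters, sequence motifs and the entpd5a locus. No annotation or sequence of the build of these files was used here, so genes, promoters, motifs and that locus are not analysed here and no coordinate is given a gene name. The gene model was applied to windows in place of genes, a choice made after the files were seen. The rule for named genes was replaced likewise. Per contrast and direction, the 5 regions with the lowest mean rank among those on chromosomes with no summit of the other group within 1000 bp in its full lists were named, filled up with the other separating regions of lowest mean rank. The neighbour condition was added after the values under a first rule were seen, because a single peak whose summit shifts can fall in neighbouring regions. The 3 windows with the most separating regions and the 5 windows with the smallest p past the threshold were also eligible, and the text gives a part of each set.

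Both procedures were tested on simulated data. For head against trunk osteoblasts, lists drawn from 133213 regions, with normal noise of SD 0.5 on the log2 rank and no group difference, gave 305 separating regions at a mean Jaccard index of 0.602 within groups, so part of each count of separating regions can come from noise. With 200 regions lowered in trunk osteoblasts by 1, 2 and 3 on the log2 scale of rank, 13.5%, 38.0% and 51.5% of them were recovered. Counts of 9407 windows were simulated as independent Poisson draws, so their rates hold for such noise only. Deviations of real libraries from the window model correlated up to 0.63, in part because fitting group means and list length itself makes deviations correlate. For the same contrast limma made 0 calls without a change in the simulated windows and recovered 2%, 17.5% and 63% of 200 windows raised 2, 3 and 4-fold in head osteoblasts. Most simulated changes of 2 and 3-fold were thus not called.

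Alternatives were full lists, lists of 5000 summits, merge distances of 100 and 500 bp, scores of at least 5, a pseudocount of 1, no filter on low values, no covariate, the replicate number as a block and each library left out in turn. Those of the window model had been set for the gene model and were applied to windows, like the window model itself, after the files were seen. Also added then were windows of 50 and 250 kb, a block by the number in the peak names, absence from the other group's full lists, no other-group summit within 1000 bp, and the libraries described without file loss. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, figures matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.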

Results

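Chromatin accessibility was profiled in skeletal cells of zebrafish at 15 days post fertilisation by ATAC-seq, an assay in which a transposase inserts sequencing adapters into open chromatin. Cells were sorted by fluorescence from fish carrying a green reporter driven by entpd5a, a gene expressed in bone-forming osteoblasts, and a red reporter driven by an enhancer of the cartilage collagen gene col2a1a. Osteoblasts were green and not red, and chondrocytes, the cells of cartilage, were red and not green. Each cell type was taken from the head and from the trunk. The labels call the head osteoblasts classical and the trunk osteoblasts non-classical, and the trunk chondrocytes are described as lying between spinal segments. The 4 groups held 3 libraries each, labelled as biological replicates.

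The values analysed were lists of accessibility summits, the single base of highest signal in each called peak. The 12 lists held 546075 summits and differed widely in length. Head osteoblast lists held 56181 ± 25215 summits (SD, n = 3), trunk osteoblast lists 36466 ± 24136, head chondrocyte lists 59040 ± 17889 and trunk chondrocyte lists 30338 ± 23577. The shortest list, of trunk chondrocyte replicate 3, held 8407 summits and the longest, of head chondrocyte replicate 1, held 79517. Summits of all libraries within 250 bp of each other were joined into 133213 regions with a median width of 41 bp, of which 5283 (3.97%) held a summit in all 12 libraries and 43176 (32.4%) in 1 library. Because list length differed widely within groups, each library was reduced to its strongest summits, as many as the shortest list of the libraries compared.

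**Figure D1:**
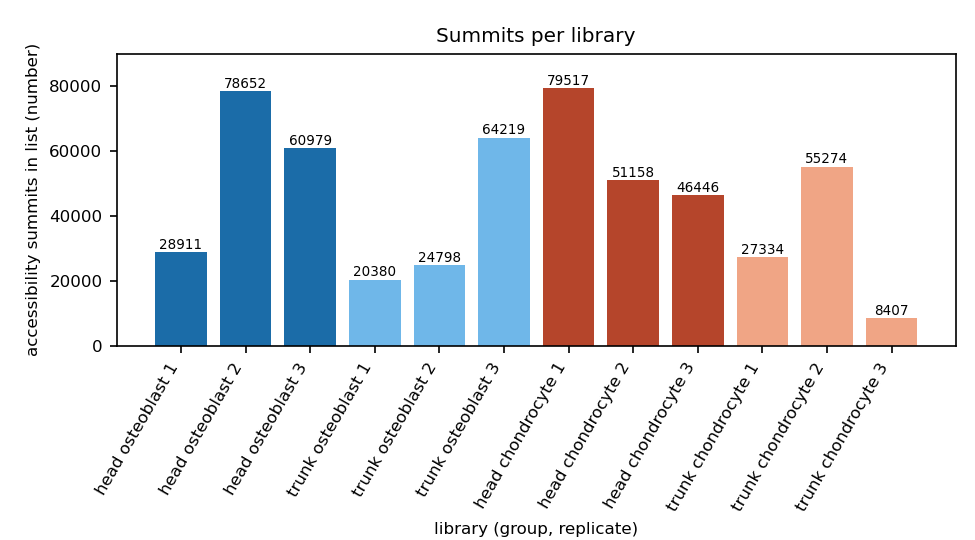
Number of accessibility summits (vertical axis, starting at 0) in the deposited list of each of the 12 libraries (bars, coloured by group). Lists ranged from 8407 summits in trunk chondrocyte replicate 3 to 79517 in head chondrocyte replicate 1, and those of trunk osteoblasts alone from 20380 to 64219.

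At equal list length, libraries of one group shared more open regions on average than libraries of different groups, and those of different cell type shared fewer than those of different body location. At 8407 summits per library, the mean Jaccard index (shared regions divided by all regions of a pair of libraries) was 0.706 among head osteoblasts, 0.618 among trunk osteoblasts, 0.716 among head chondrocytes and 0.585 among trunk chondrocytes. Between head and trunk it was 0.577 for osteoblasts and 0.578 for chondrocytes. Between osteoblasts and chondrocytes it was 0.428 in the head and 0.409 in the trunk. The mean index within groups exceeded that between groups by 0.189, and an exact permutation test over the 15400 partitions of the libraries into 4 groups of 3 gave a one-sided p of 6.5e-05, the smallest these partitions can give. With the lists at full length the excess was 0.065 (exact one-sided p = 0.031), and the order of groups changed in part. Head osteoblasts then had a mean index of 0.388 with head chondrocytes and 0.376 with trunk osteoblasts. Trunk chondrocytes had 0.283 among themselves, 0.362 with head chondrocytes and 0.314 with trunk osteoblasts.

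For 11 of the 12 libraries the most similar library belonged to the same group. The exception was trunk osteoblast replicate 3, which was closest to head osteoblast replicate 2, with a Jaccard index of 0.666. With full lists, 6 of the 12 libraries were closest to their own group.

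**Figure D2:**
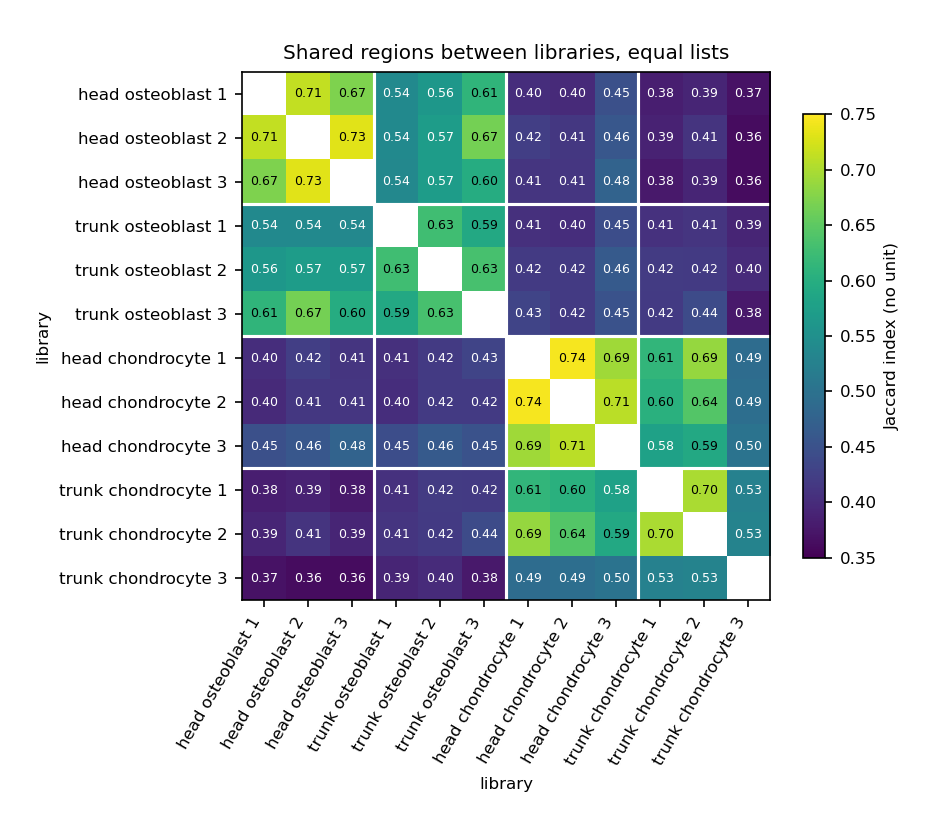
Jaccard index (colour, no unit) of the regions of each pair of the 12 libraries, with every library at its 8407 strongest summits; white lines part the 4 groups. Pairs of different cell type have the lowest values, with means from 0.382 to 0.428, while head and trunk of one cell type have means of 0.577 and 0.578.

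At equal list length the most frequent classes of open regions were those shared by all groups and by the 2 chondrocyte groups. Of 13540 regions with a summit in at least 2 of the 3 libraries of some group at 8407 summits per library, 4088 (30.2%) were open in all 4 groups. Both chondrocyte groups and no osteoblast group held 1746 (12.9%), and both osteoblast groups and no chondrocyte group held 1311 (9.7%). The 2 head groups alone shared 198 regions (1.5%) and the 2 trunk groups alone 212 (1.6%). Regions open in a single group numbered 1469 in head osteoblasts, 1018 in trunk osteoblasts, 990 in head chondrocytes and 942 in trunk chondrocytes. With full lists, which are longer on average in the head, the classes differed: of 74065 regions, head osteoblasts alone held 16647 (22.5%), all 4 groups 14542 (19.6%), the 2 head groups alone 9718 (13.1%) and the 2 trunk groups alone 211 (0.3%).

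**Figure D3:**
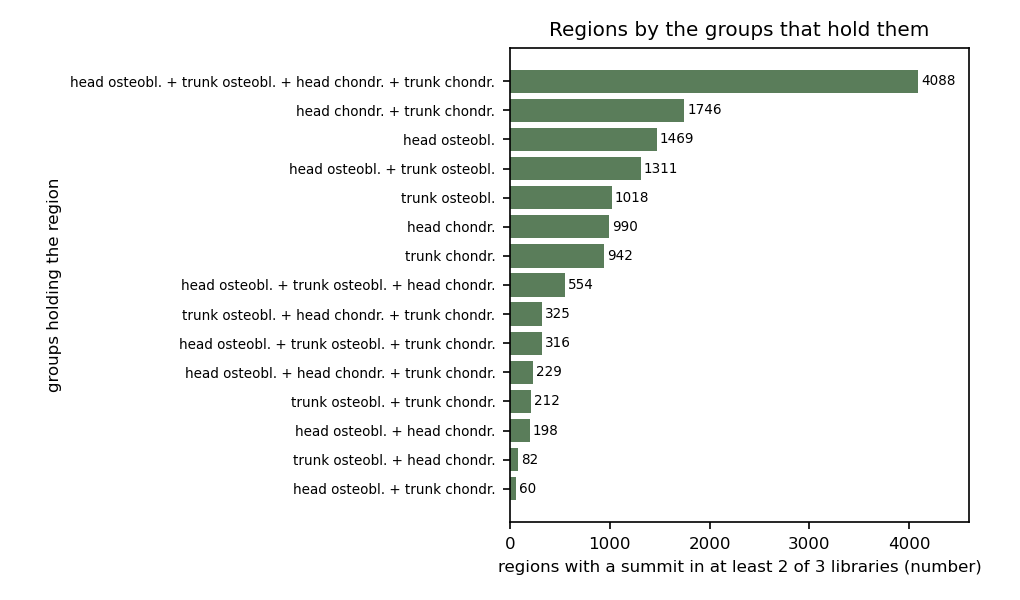
Number of regions (horizontal axis, starting at 0) by the combination of groups that held them, a group holding a region when at least 2 of its 3 libraries had a summit there at 8407 summits per library. Regions of all 4 groups (4088) and of the 2 chondrocyte groups (1746) were the most frequent, and those of the 2 head groups (198) or the 2 trunk groups (212) were among the rare ones.

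The comparison of head with trunk osteoblasts asked how chromatin differs between classical and non-classical osteoblasts. At 20380 summits per library, 9844 regions were open in all 6 osteoblast libraries. In contrast, 1093 regions were open in every head osteoblast library and in no trunk osteoblast library, and 1023 were open in every trunk and no head osteoblast library. The shared regions lay higher in the ranked lists, with a mean median rank of 5329, against 13551 for head-only and 11878 for trunk-only regions.

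The strongest head-only osteoblast regions without a trunk osteoblast summit within 1000 bp included chromosome 9, 30141197 to 30141287 (GRCz11), with ranks between 3063 and 9223. It was open in 3 of 3 head osteoblast libraries and in no library of the other 3 groups, also with full lists. Chromosome 17, 49820474 to 49820528, and chromosome 18, 9875358 to 9875379, showed the same distribution. Another such region, chromosome 9, 46689213 to 46689309, was also open in 3 of 3 head chondrocyte libraries. The strongest trunk-only osteoblast region by the same rule was chromosome 12, 2595818 to 2595984, with ranks between 3341 and 6028, followed by chromosome 3, 26093124 to 26093160. In both, all 3 trunk and no head osteoblast libraries held a summit, and with full lists the first also held one in 2 of 3 trunk chondrocyte libraries and the second in 1 head and 1 trunk chondrocyte library.

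Some 100 kb windows held several of these regions. A window on chromosome 9 from 3300001 to 3400000 held 6 head-only osteoblast regions, and one on chromosome 9 from 21000001 to 21100000 held 5 trunk-only ones. Regions that separated head from trunk osteoblasts made up 48.8% of the 4337 regions held by exactly 3 of the 6 libraries, where chance gives 10.0%. Of the regions that separated the head from the other 2 trunk osteoblast libraries in the head direction, trunk osteoblast replicate 3 held 46.6%. Replicates 1 and 2, each measured on its own set, held 13.6% and 17.9%, and those sets left out regions of replicate 3. The split between directions depended on list length: 51.7% of the separating regions were head-only with equal lists and 80.8% with full lists (1156 head-only and 275 trunk-only). The count of separating regions rose from 2116 to 3742 without trunk osteoblast replicate 3 and to 3574 without trunk osteoblast replicate 1, where lists were also longer (24798 summits). At a fixed list length, leaving out libraries can only keep or raise a count of separating regions, because fewer libraries must hold or lack a region. Of the separating regions, 269 had no summit in the full lists of the other group. From the libraries described without file loss, where lists were longer (24798 summits), 5179 regions separated the groups. In the limma model of regions per 100 kb window, 0 of 9407 windows changed between head and trunk osteoblasts, with 787 at an unadjusted p below 0.05. Without trunk osteoblast replicate 3 that model called 44 windows, of which 39 were higher in the head, and without head osteoblast replicate 2 it called 1. With lists of 8407 summits and no covariate it called 87 of the 3503 windows then tested.

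Head osteoblasts and head chondrocytes were separated by the most regions of the 4 pairs of groups compared, also with all lists at 8407 summits (1300 and 1833). At 28911 summits per library, 3955 regions were open in every head osteoblast and no head chondrocyte library, and 4914 in every head chondrocyte and no head osteoblast library. Of these, 3017 had no summit at all in the full lists of the other group. Separating regions made up 83.3% of the 10650 regions held by exactly 3 of the 6 libraries, where chance gives 10.0%.

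The separating regions lay in the middle of their lists, with a mean median rank of 14949 for head osteoblast-only and 15203 for head chondrocyte-only regions, against 8005 for regions of all 6 libraries. The regions named here were taken for their low mean rank. Chromosome 8, 25198968 to 25199004, had ranks between 975 and 1771 in the 3 head osteoblast libraries, was open in all 3 trunk osteoblast libraries and had no summit in the 6 chondrocyte libraries. Chromosome 7, 27432730 to 27432807, had the same distribution, with ranks between 1880 and 4574. Chromosome 4, 13635873 to 13635893, had ranks between 1759 and 2135 in head chondrocytes, was open in all 6 chondrocyte libraries and was in no osteoblast list. Chromosome 14, 4937022 to 4937118, was likewise open in all 6 chondrocyte libraries, but with full lists it also appeared in 1 trunk osteoblast library.

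The windows with the most head osteoblast-only regions lay on chromosome 17 from 45000001 to 45100000 and on chromosome 7 from 65500001 to 65600000, with 8 each. Windows on chromosome 4 from 17000001 to 17100000 and on chromosome 7 from 48700001 to 48800000 held 8 head chondrocyte-only regions each. In the limma model 37 windows changed, 27 higher in head osteoblasts and 10 higher in head chondrocytes. On lists of 8407 summits without the covariate the balance turned, with 549 of 3503 windows, 239 higher in head osteoblasts and 310 in head chondrocytes. A window on chromosome 13 from 32000001 to 32100000 held 14.33 ± 8.33 regions in head osteoblasts and 2.67 ± 0.58 in head chondrocytes (SD, n = 3), a log2 difference of 2.21 ± 0.31 (SE; limma adjusted p = 0.0084) after adjustment for list length. One on chromosome 16 from 16600001 to 16700000 held 1.67 ± 1.53 and 8 ± 1 regions, a log2 difference of -2.19 ± 0.41 (limma adjusted p = 0.042). In both windows all 3 libraries of the higher group lay above all 3 of the other. The count of changed windows was 0 without head osteoblast replicate 1 or 3, 1 without head chondrocyte replicate 2, 4 without head osteoblast replicate 2 or head chondrocyte replicate 3, 17 without trunk chondrocyte replicate 2 and 228 without trunk chondrocyte replicate 3. It was also 0 with the number in the peak names as a block. The count of separating regions was 15406 without head osteoblast replicate 1, of which 8585 were head osteoblast-only. That library had the shortest of the 6 lists, so lists were then longer (46446 summits). It was also the only one of the 6 described with file loss.

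**Figure D4:**
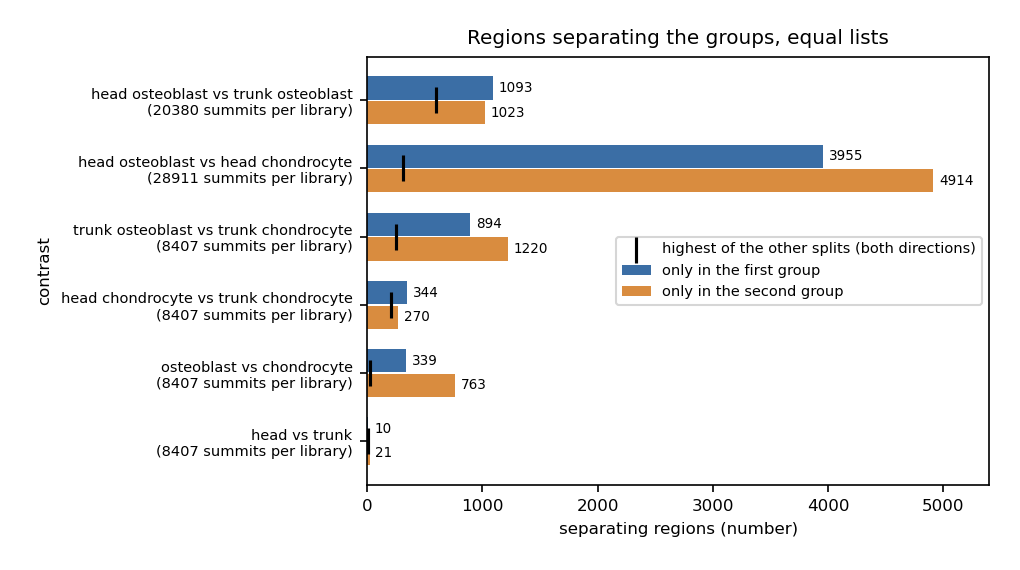
Regions open in every library of one group and no library of the other (bars, number of regions from 0), for 6 contrasts at the list length given in brackets; black ticks mark the highest total, both directions together, from another split of the same libraries. Head osteoblasts against head chondrocytes gave the most regions (3955 and 4914) and head against trunk the fewest (10 and 21); list lengths differ between contrasts, so bars of contrasts with different lengths are not comparable in size.

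In the trunk, 894 regions were open in every osteoblast and no chondrocyte library and 1220 in every chondrocyte and no osteoblast library, at 8407 summits per library. Only 53 of the osteoblast-only and 202 of the chondrocyte-only regions had no summit in the full lists of the other group. Chondrocyte-only regions lay higher in their lists, with a mean median rank of 3698 against 5036 for the osteoblast-only regions. The whole list of trunk chondrocyte replicate 3 was used, down to a score of 1.31, against 9.61 to 65.12 in trunk osteoblast libraries. The difference in rank was not separated from the depth of that library. Chromosome 13, 44860742 to 44860836, had ranks between 415 and 1143 in the 3 trunk chondrocyte libraries and no trunk osteoblast summit with full lists. Chromosome 21, 42806913 to 42807043, ranked between 371 and 1245, again with no trunk osteoblast summit. Both were among the strongest 8407 summits of all 3 head chondrocyte libraries, and with full lists both had a summit in all 3 head osteoblast libraries. Among trunk osteoblast-only regions, chromosome 18, 48263563 to 48263636, ranked between 1195 and 3408 and was also open in 3 of 3 head osteoblast libraries. With full lists it had a summit in all 3 head chondrocyte libraries too.

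A window on chromosome 21 from 6400001 to 6500000 held 5 trunk osteoblast-only regions, and windows on chromosome 18 from 46300001 to 46400000 and chromosome 7 from 48700001 to 48800000 held 5 trunk chondrocyte-only regions each. In the limma model 318 windows changed, 139 higher in trunk osteoblasts and 179 higher in trunk chondrocytes. A window on chromosome 5 from 16200001 to 16300000 held 9.67 ± 4.62 regions in trunk osteoblasts and 1.67 ± 2.08 in trunk chondrocytes (SD, n = 3), a log2 difference of 2.24 ± 0.26 (SE; limma adjusted p = 0.0018). One on chromosome 17 from 41900001 to 42000000 held 1.67 ± 1.15 and 8.33 ± 4.04 regions, a log2 difference of -2.4 ± 0.33 (limma adjusted p = 0.0025). In both windows all 3 libraries of the higher group lay above all 3 of the other.

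Separating regions made up 72.2% of the 2927 regions held by exactly 3 of these 6 libraries, where chance gives 10.0%. Osteoblast-only regions were 42.3% of them with equal lists and 70.8% with full lists. Without trunk chondrocyte replicate 3 the count rose from 2114 to 6090, of which 2189 were osteoblast-only, but lists were then longer (20380 summits). The count of changed windows was 56 without trunk osteoblast replicate 2, 71 without trunk osteoblast replicate 1, 85 without trunk chondrocyte replicate 1, 175, 192 and 200 without head chondrocyte replicate 2, 1 and 3, and 624 without trunk osteoblast replicate 3. From the libraries described without file loss it was 0, with 1589 windows at an unadjusted p below 0.05 in limma, while with file loss as a term of the model it was 485 and with the number in the peak names as a block 149.

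Head and trunk chondrocytes were separated by fewer regions than osteoblasts and chondrocytes of the trunk at the same list length. At 8407 summits per library 344 regions were open in every head and no trunk chondrocyte library, 270 in every trunk and no head chondrocyte library, and 4439 in all 6. Chromosome 4, 25488907 to 25488965, ranked between 6365 and 8026 in head chondrocytes and was in no list of the other 3 groups. Chromosome 20, 34487223 to 34487419, ranked between 4187 and 7617 in trunk chondrocytes and was in no head list of either cell type, but with full lists it was in 2 of 3 trunk osteoblast lists. Only 11 of the 614 separating regions had no summit in the full lists of the other group. Separating regions were 40.8% of the 1505 regions held by exactly 3 of the 6 libraries, where chance gives 10.0%.

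The direction could not be read from full lists, where 99.3% of the separating regions were head-only (3183 and 21), against 56.0% with equal lists. Without trunk chondrocyte replicate 3 there were 3167 separating regions, 1594 head-only and 1573 trunk-only, but lists were then longer (27334 summits). Without trunk chondrocyte replicate 2 there were 1038. In limma 0 windows changed, with 469 at an unadjusted p below 0.05, 1 window was called without trunk chondrocyte replicate 2, and the equal-list model without covariate called 47 of 3503.

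Across both locations, 339 regions were open in all 6 osteoblast and no chondrocyte libraries and 763 in all 6 chondrocyte and no osteoblast libraries, at 8407 summits per library. Only 3 of the osteoblast and 22 of the chondrocyte regions had no summit in the full lists of the other cell type. Separating regions were 67.3% of the 1637 regions held by exactly 6 of the 12 libraries, where chance gives 0.216%. The chondrocyte regions chromosome 4, 13635873 to 13635893, chromosome 2, 36613526 to 36613544, and chromosome 10, 37229 to 37250, were open in 6 of 6 chondrocyte libraries and in no osteoblast list at full length. The strongest osteoblast region by mean rank, chromosome 2, 3545213 to 3545294, ranked between 553 and 1251 in the 6 osteoblast libraries. With full lists, it also had a summit outside the strongest 8407 in 3 head and 2 trunk chondrocyte libraries. Chromosome 19 held an osteoblast region at 40983179 to 40983249 and, close by, a chondrocyte region at 40985383 to 40985449, each open in all 6 libraries of its cell type. With full lists, the osteoblast region also had a summit in 3 head and 2 trunk chondrocyte libraries, and the chondrocyte region had none in osteoblast libraries.

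In the limma model 894 windows changed between the cell types, 408 higher in osteoblasts and 486 higher in chondrocytes. A window on chromosome 12 from 3100001 to 3200000 was higher in osteoblasts, with a log2 difference of 1.84 ± 0.23 (SE; limma adjusted p = 0.00062). It held 14.67 ± 3.51 regions in head and 8.33 ± 6.66 in trunk osteoblasts, and 3.33 ± 0.58 and 2.67 ± 3.79 in head and trunk chondrocytes (SD, n = 3). A window on chromosome 5 from 25100001 to 25200000 held 1 region in each head osteoblast library and 0 in each trunk osteoblast library, against 6.33 ± 3.21 in head and 3 ± 2 in trunk chondrocytes, a log2 difference of -2.42 ± 0.32 (limma adjusted p = 0.00086).

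The regions of the head contrast were largely found again in the trunk libraries of the same cell type. Of 1300 regions open in every head osteoblast and no head chondrocyte library at 8407 summits, 58.4% ± 10.3 were found in trunk osteoblast libraries and 9.7% ± 2.0 in trunk chondrocyte libraries (SD, n = 3). Of 1833 head chondrocyte-only regions, 73.4% ± 10.0 were found in trunk chondrocyte and 11.7% ± 1.9 in trunk osteoblast libraries. In each of these comparisons every library of the matching cell type lay above every library of the other. An exact permutation test of 3 against 3 libraries can give no two-sided p below 0.1.

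Osteoblast-only regions were 30.8% of the separating regions with equal lists and 58.8% with full lists (164 and 115). Without trunk chondrocyte replicate 3 there were 2591 separating regions, of which 749 were osteoblast-only, but lists were then longer (20380 summits). The count of changed windows was 381 and 480 without head chondrocyte replicate 2 and 3, 532 and 541 without head osteoblast replicate 1 and 3, and 343 from the libraries described without file loss. Without the list-length covariate, limma called 0 windows on full lists in this and every other contrast, with 335 here at an unadjusted p below 0.05, and on lists of 8407 summits it called 850 of 3503.

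Body location separated few regions in both cell types at once. In the separate contrasts, 12 regions were head-only and 37 trunk-only in osteoblasts as well as chondrocytes, where independent lists would share 2.8 and 5.0. At 8407 summits per library 10 regions were open in all 6 head and no trunk libraries and 21 in all 6 trunk and no head libraries. These were 1.9% of the 1637 regions held by exactly 6 of the 12 libraries, where chance gives 0.216%. The strongest trunk region was chromosome 23, 36052770 to 36052858, with ranks between 1177 and 6092 in the 6 trunk libraries. With full lists it had a summit in 1 of 3 head osteoblast libraries and in no head chondrocyte library. The head region chromosome 20, 10111152 to 10111195, was open in all 6 head libraries and, with full lists, in 1 of 3 trunk osteoblast and no trunk chondrocyte libraries. None of the 31 regions was absent from all full lists of the other location. Without trunk chondrocyte replicate 3, where lists were longer (20380 summits), the count rose to 170, 60 in the head and 110 in the trunk. With full lists 95.9% of 74 separating regions were head-only, against 32.3% with equal lists.

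The limma model called 2 windows, both higher in the trunk. On lists of 8407 summits without the covariate it called 116 of 3503, of which 49 were higher in the head and 67 in the trunk. The window on chromosome 3 from 23600001 to 23700000 had a log2 difference between head and trunk of -1.5 ± 0.21 (SE; limma adjusted p = 0.018). The window on chromosome 23 from 36000001 to 36100000, which holds the trunk region above, had one of -1.89 ± 0.29 (limma adjusted p = 0.031). Before adjustment for list length, the second held 15 ± 9.17 regions in trunk and 6.67 ± 5.51 in head osteoblasts, and 10.33 ± 7.51 in trunk and 10 ± 7.94 in head chondrocytes (SD, n = 3), so its raw means in chondrocytes hardly differed. Neither passed without head osteoblast replicate 1, head chondrocyte replicate 2 or 3, or trunk chondrocyte replicate 1 or 2 (0 windows each). Without trunk osteoblast replicate 1, 2 or 3 only the window on chromosome 3 passed, and neither passed with the replicate number as a block, a merge distance of 500 bp or the libraries described without file loss.

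**Figure D5:**
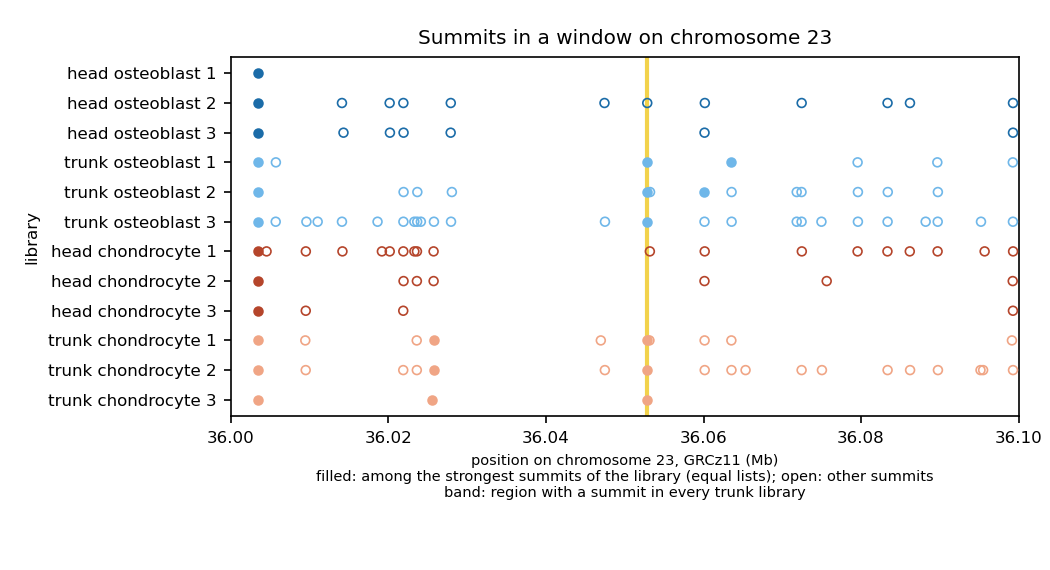
Positions of summits (circles) in each of the 12 libraries (1 line each) across chromosome 23 from 36000001 to 36100000 (horizontal axis in Mb, GRCz11); filled circles are among the 8407 strongest summits of their library, open circles are weaker, and the band marks the region from 36052770 to 36052858. In the band all 6 trunk libraries have a filled circle, and 1 head osteoblast library has an open one.

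Whether the difference between osteoblasts and chondrocytes itself differed between head and trunk was tested as an interaction. In limma 0 of 9407 windows passed, with 636 at an unadjusted p below 0.05. Without trunk osteoblast replicate 3, 4 passed, and the equal-list model without covariate called 85 of 3503. Recovery was simulated for head against trunk osteoblasts only, where 2% and 17.5% of 2 and 3-fold changes were called. The count of 0 therefore does not show that the difference was the same in head and trunk. With all 12 lists at 8407 summits, 339 regions separated osteoblasts from chondrocytes in the osteoblast direction in both head and trunk, where independent lists would share 64.7. In the chondrocyte direction 763 did so, where independent lists would share 149.1. The 2 contrasts share no library. Regions of opposite direction numbered 7 and 0, where independent lists would share 101.7 and 94.9. With the head contrast at 28911 and the trunk contrast at 8407 summits, 106 and 403 regions were shared in the same direction (43.3 and 114.8 for independent lists) and 2 and 0 in opposite directions (83.4 and 59.6). Without trunk chondrocyte replicate 3, at 20380 summits, 749 and 1842 were shared in the same direction (147.3 and 397.7) and 13 and 6 in opposite directions (211.9 and 276.5).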

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

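Chosen only after the result was seen were the counts of regions of opposite direction and the tests of list length, of another trunk cell type, of position along the body and of a cleaner list, and the ratios for single libraries.

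Some regions separated head from trunk, or osteoblasts from chondrocytes, in opposite directions in the paired contrasts, a difference that was not tested region by region. In the location contrasts, 6 regions were open in every trunk and no head osteoblast library but in every head and no trunk chondrocyte library, where independent lists would share 6.4. The opposite held for 1 region (chromosome 7, 48654307 to 48654369), where 2.2 would be shared. In the cell type contrasts, 2 regions were open in every head chondrocyte and no head osteoblast library but in every trunk osteoblast and no trunk chondrocyte library, where 83.4 would be shared, 1 of them at chromosome 13, 32860895 to 32861020. These contrasts used different list lengths, and each of these regions had summits in some libraries of all 4 groups with full lists.

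Trunk-only regions were shared by osteoblasts and chondrocytes more often than independent lists would give, 37 against 5.0, a ratio of 7.4. List length alone is argued against, since with all 12 lists at 8407 summits the ratio was 6.8. Equal lists do not equalise the depth behind the ranks, so a difference in depth stays open. The score at rank 8407 was 1.31 in trunk chondrocyte replicate 3 and 171.78 in head chondrocyte replicate 1. With full lists, each of the 37 regions also had a summit in some head library. All but chromosome 23, 36052770 to 36052858, had one in head chondrocyte libraries. The 37 regions were thus trunk-only by rank within lists and not by absence from full lists. Cells of the other type in the trunk sorts stay open. Regions of all 6 osteoblast and no head chondrocyte libraries were found in trunk chondrocyte libraries at 16.4% ± 3.1 (SD, n = 3), against 40.3% ± 4.9 for trunk-only osteoblast regions. The reverse test gave 14.5% ± 2.3 against 32.3% ± 1.5. In each test only the first set left out regions of the head libraries of the other cell type. Of the trunk-only osteoblast regions, 31.3% ± 1.8 were found in head chondrocyte libraries. A lower first value is thus partly built in, and these tests cannot decide. The bound set before these tests was under 0.5 of the second value beyond the spread of the libraries. Both means lay under 0.5 of the second value, but library by library the bound was met by neither test. The ratios were 0.321, 0.356 and 0.575 in trunk chondrocyte replicates 1, 2 and 3 and 0.518, 0.482 and 0.349 in trunk osteoblast replicates 1, 2 and 3. Another trunk cell type in both sorts also stays open for the 37 regions, and position along the body, which the design names, is a candidate explanation, with head-only regions shared at a ratio of 4.2. The labels call trunk osteoblasts non-classical and place trunk chondrocytes between spinal segments. Body position and the kind of cell sorted therefore cannot be told apart here.

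Trunk osteoblast replicate 3 was the only library whose most similar library belonged to another group at equal list length. A head osteoblast library under a trunk label is argued against. Trunk osteoblast replicate 3 held 60.4% of the trunk-only regions that separated the other 2 trunk osteoblast libraries from the head ones. Head osteoblast libraries, left out in turn, held 14.4% to 16.0% of the trunk-only regions then defined. Trunk osteoblast replicate 3 also held 46.6% of the head-only regions, against 13.6% and 17.9% for trunk osteoblast replicates 1 and 2. The sets differed, with 2048, 1265 and 1331 regions, because each was defined without the library measured. Those for replicates 1 and 2 left out all regions of replicate 3, so the definition can widen the gap. Some head-type osteoblasts among the cells of replicate 3 are a candidate explanation that these shares cannot decide. Its mean Jaccard index exceeded that of the other 2 by 0.072 to head osteoblasts and by 0.006 to chondrocytes, which goes against a cleaner list of the same cells. That explanation stays open, because its 60.4% of trunk-only regions lay beside 60.5% and 73.9% in the other 2, and its index to them, 0.592 and 0.633, beside the 0.628 between them.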

How the results depend on the processing

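All alternatives for windows were chosen after the files were seen, as were file loss, absence from full lists and the 1000 bp neighbour condition, and the cause of a change was not tested unless given. The excess similarity within groups kept its direction and its side of 0.05 throughout (0.065 with full lists, 0.175 to 0.202 with 1 library left out). Merge distances of 100 and 500 bp and the neighbour condition kept all 6 counts of separating regions within 1.5 times. Counts below follow the order head against trunk osteoblasts, head osteoblasts against head chondrocytes, trunk osteoblasts against trunk chondrocytes, head against trunk chondrocytes, cell type, location. At 5000 summits separating regions were 378, 1822, 1200, 300, 660 and 6, as shorter lists hold fewer regions. Absent from the other group's full lists were 269, 3017, 255, 11, 25 and 0. With full lists, the last 4 were 1306, 3204, 279 and 74. From libraries described without file loss, 5179, 15406 and 48 regions separated the first 2 contrasts and location. Lists of the first 2 were then longer (24798 and 46446 summits). With 1 library left out the ranges were 2715 to 3742, 9822 to 15406, 2448 to 6090, 810 to 3167, 1119 to 2591 and 34 to 170. Leaving out libraries can only keep or raise these counts at a fixed list length, so a rise alone does not mark a library as unusual. The highest value in 4 of them came without trunk chondrocyte replicate 3, whose list is the shortest. The lists compared were then longer, at 20380 or 27334 summits.

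Changed windows depended more on the settings. The number tested differed too: 9407 in the main model, 3503 on equal lists without covariate, 13889 at 50 kb and 4651 at 250 kb. Counts from these settings are not comparable in size. Without covariate on full lists limma called 0 in all 7 contrasts, with 333, 138, 239, 1366, 335 and 2244 at an unadjusted p below 0.05 and 46 for the interaction. On equal lists without covariate it called 87 for head against trunk osteoblasts, 549 for head osteoblasts against head chondrocytes, 47 for head against trunk chondrocytes, 116 for location and 85 for the interaction. Head against trunk osteoblasts had 3 at scores of at least 5 and 1 with a pseudocount of 1 or no filter. Head osteoblasts against head chondrocytes had 16 and 56 at merge distances of 100 and 500 bp, 131 with a pseudocount of 1, 59 without filter, 19 in 50 kb windows and 14 without the libraries with file loss. Trunk osteoblasts against trunk chondrocytes had 485 with file loss as a term and 0 without those libraries, where fewer libraries were left. Cell type had 562 of 4651 in 250 kb windows and 343 of 9407 without those libraries, beside 894 of 9407 in the main model. Location had 0 at 500 bp and without those libraries, and 1 in 50 and in 250 kb windows. With 1 library left out the ranges were 0 to 44, 0 to 228, 56 to 624, 0 to 1, 381 to 1029, 0 to 2 and, for the interaction, 0 to 4.

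Deviations of same-numbered libraries correlated between -0.33 and 0.63, with 5 of 18 pairs over 0.1, so the replicate number was not used as a pairing over all groups. For trunk osteoblasts and trunk chondrocytes all 3 pairs were over 0.1 (0.11, 0.13 and 0.63). These deviations were left after fitting group means and list length, and that fit itself makes deviations correlate according to list length. The pair at 0.63 joined the longest trunk osteoblast list (64219 summits) with the shortest trunk chondrocyte list (8407). The correlations therefore cannot decide on pairing, which stays open there. The replicate block gave 348 windows for that contrast against 318, 18 for head osteoblasts against head chondrocytes, 0 for location, and moved no other count by over 1.5 times. The block by the number in the peak names gave 0 for head osteoblasts against head chondrocytes, 149 for trunk osteoblasts against trunk chondrocytes, 525 for cell type and 1 for location.

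Of named regions, 194 of the values under alternatives still separated the groups and 46 did not (with full lists the 40 that did were fixed by the naming rule), and of named windows 583 passed and 137 did not, none with a change of direction. Alternatives set for gene, gene list, promoter and motif results were not run, since no annotation or sequence of this build was used. The number of summits in the shortest list compared limits the counts of separating regions.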

Other observations

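The test of regions counted once within 5000 bp was set before its result was seen, and all other tests of this part were chosen after it.

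Regions separating head osteoblasts from head chondrocytes lay in groups along the chromosomes. In this contrast, 306 windows of 100 kb held 3 or more head osteoblast-only regions, and 317 held 3 or more head chondrocyte-only regions. Random draws of as many regions from those with a summit in any library compared gave at most 164 and 264 windows in 200 draws. This argues against uneven density of all such regions. The draws were not matched for rank or for the number of libraries holding a region. Uneven density of regions held by every library of a group therefore stays open. With regions within 5000 bp of each other counted once, 255 and 251 windows were left, against at most 129 and 212 in the draws. Broad sites split into several regions are thus argued against as the whole cause of the excess over these draws. A candidate explanation is that several elements around one locus open together in one cell type, and without an annotation it was not tested. In the trunk, 37 windows held 3 or more chondrocyte-only regions, against at most 19 in 1000 draws, but 10 held 3 or more osteoblast-only regions, against at most 12.

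Trunk-only osteoblast regions were found in chondrocyte libraries more often than head-only ones. Of 386 such regions at 8407 summits, 40.3% ± 4.9 were found in trunk chondrocyte and 31.3% ± 1.8 in head chondrocyte libraries (SD, n = 3). Of 362 head-only osteoblast regions, 10.3% ± 1.0 were found in trunk and 18.2% ± 1.7 in head chondrocyte libraries. Without trunk chondrocyte replicate 3 and at 20380 summits, the values were 43.1% and 29.6% for 1023 trunk-only regions and 15.8% and 25.8% for 1093 head-only regions.

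The 3 libraries described with file loss did not stand together. Head and trunk osteoblast replicate 1 had a Jaccard index of 0.54, within the 0.536 to 0.666 of the other pairs of these groups. Head osteoblast and trunk chondrocyte replicate 1 had 0.383 (others 0.364 to 0.41), and trunk osteoblast and trunk chondrocyte replicate 1 had 0.407 (others 0.377 to 0.441).

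Other splits of the same libraries bear on whether the counts could arise from chance. For separating regions of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 2116 for head against trunk osteoblasts (highest other 594, the split that put head osteoblast replicate 1 with trunk osteoblast replicates 1 and 2, the 3 short lists), 8869 for head osteoblasts against head chondrocytes (308), 2114 for trunk osteoblasts against trunk chondrocytes (246) and 614 for head against trunk chondrocytes (207). In each of these, 1 of the 10 splits, the real one, gave as many. With full lists another split exceeded the real one in 3 of these contrasts, by the most for head against trunk osteoblasts, where the split of the 3 short lists gave 13158 against the real 1431. For 6 against 6 libraries, 1 of 100 splits, the real one, gave as many as the real 1102 for cell type (highest other 26). For location, 1 of 100 gave as many as the real 31 (highest other 7). This is the smallest share that 100 splits can give, and it argues against chance for cell type at equal list length. These splits did not keep the cell types balanced, so for location they are unlike groupings and do not decide. With full lists the real 279 for cell type was reached by 3 of 100 splits (highest other 954) and the real 74 for location by 4 of 100 (highest other 448). These shares are under 0.05 too, but splits that call several times the real count point to a structure of the full lists.

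For changed windows, 1 of 10 splits gave as many as the real 37 for head osteoblasts against head chondrocytes (highest other 0) and 1 of 10 as many as the real 318 for trunk osteoblasts against trunk chondrocytes (highest other 1), again too few splits for a share under 0.05. The counts of 0 for head against trunk osteoblasts (highest other 2) and for head against trunk chondrocytes (highest other 0) were reached by all 10 splits, as a count of 0 always is. For cell type 1 of 100 splits reached the real 894 (highest other 64), the smallest share that 100 splits can give, which argues against chance. For location 3 of 100 splits reached the real 2, a share under 0.05. The split that called 13 put head osteoblast replicate 1, trunk osteoblast replicates 1 and 2, head chondrocyte replicate 2 and trunk chondrocyte replicates 1 and 2 on one side. It points to a structure of the libraries that was not tested. The interaction count of 0 was reached by all 100 splits (highest other 64), as a count of 0 always is, so these splits decide nothing there.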
